A study of Mus musculus with 8 samples.

How the data were processed

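Single-nucleus RNA was measured in frontal cerebral cortex, with the mice, groups and doses given under Results. Per the labels, nuclei were isolated from frozen tissue and 10x Single Cell 3' v3 libraries were prepared. The authors deposited unfiltered matrices of UMI counts for 32285 genes, with no normalization. They were aligned to mm10 and counted with Cell Ranger 7.0.1 per the submitters' processing notes, while the file headers name Cell Ranger 4. Whether intronic reads were counted is stated in neither. No cell calls or cell types of the submitters were used, and every step below was computed here from the 8 matrices. Gene coordinates come from a copy of GENCODE vM21 (GRCm38), in which 32158 of the 32285 genes were matched by Ensembl ID, and that annotation may not be the one the authors counted with.

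Barcodes with at least 500 genes detected and under 5% mitochondrial UMIs were tested against the profile of barcodes with at most 100 UMIs by a multinomial Monte Carlo test. It used 2000 simulations, up to 4000 UMIs per barcode, seed 1 and an adjusted p under 0.001. Doublets were called per library with Scrublet at an expected rate of 6%. All 50889 candidates, before the ambient test, were clustered. Counts were normalized to 10000 per nucleus and log-transformed, and the 3000 most variable genes among those in at least 50 nuclei were scaled (maximum 10) and reduced to 30 principal components, without sex-linked and mitochondrial genes. Leiden clustering at resolution 1.5 on shared neighbours (15 per nucleus) gave 62 clusters, and 94 nuclei in clusters of fewer than 30 were placed in no class. Nuclei that failed the ambient test, the 1657 doublets among those that passed it, and clusters with over 50% doublets were removed, which left 45512 nuclei. Marker genes listed before the data were examined named the clusters. Excitatory clusters needed Slc17a7 and 1 further listed marker detected in at least 50% of nuclei and Gad2 in under 30%. Inhibitory clusters needed Gad1 or Gad2, Erbb4 and 1 further listed marker in at least 50%, Dlx6os1 in at least 20% and Meis2 in under 30%. These limits were set when the clusters were named. Clusters that met no rule, and clusters of the 6 classes with under 5 nuclei in any library, were counted as unnamed and left out of the class comparisons, as were striatal projection neurons, perivascular macrophages and vascular cells. Counts were then summed per library and class, where a class needed at least 20 nuclei in a library. The software was Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2 and igraph 0.11.9.

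Of all UMIs, 52.7 and 64.2% for vehicle, 61.2, 62.6 and 61.5% for S-2MeGlu and 71.4, 66.9 and 68.6% for R-4APA lay in barcodes that passed. The ambient test removed 25.1% of the excitatory candidates of R-4APA 3 (967 of 3859). Nuclei retained were 5685 and 6093 for vehicle, 4963, 5534 and 4592 for S-2MeGlu and 3727, 6485 and 8433 for R-4APA. In the same order the median UMIs per nucleus were 5399 and 5529, 6452, 5728.5 and 6877.5, and 7724, 5298 and 4137, and the median genes 2642 and 2694, 2995, 2739 and 3051.5, and 3264, 2583 and 2168. At this depth and number of mice, planted changes in simulated counts with the spread of these libraries were recovered in part. R-4APA against vehicle recovered between 6 and 47% of genes changed 1.5-fold and between 27 and 70% of those changed 2-fold, depending on the class. S-2MeGlu against vehicle recovered 5 to 36% and 34 to 72%, and S-2MeGlu against R-4APA 13 to 54% and 37 to 76%. Simulated data with no change gave between 0 and 8 calls per class and comparison.

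Each comparison (S-2MeGlu against vehicle, R-4APA against vehicle, S-2MeGlu against R-4APA) was made per class with edgeR 4.0.16 in R 4.3.3. The quasi-likelihood F test with robust estimation was fitted to all 8 libraries with TMM factors, filterByExpr and Benjamini-Hochberg adjustment within class and comparison, and calls needed an adjusted p under 0.05. Changes for single genes are log2 fold changes ± SE with 95% intervals, and CPM values on the log scale used a prior count of 2. The 37 gene lists, fixed before the data were examined, needed at least 5 members measured. They were tested with camera of limma 3.58.1 at a correlation between genes of 0.01, again with an estimated correlation, and with fry. Members were also adjusted over the list alone. Shares of nuclei per class were compared by exact permutation of the libraries. The similarity of the 2 compounds' fold changes, which share the vehicle libraries, was set beside 20 simulations of unchanged groups. The gene tests were tested on simulated data before use.

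The text names genes by a rule fixed before the data were examined. Per comparison and class it takes the 3 rising and 3 falling genes of smallest p among calls whose libraries do not overlap between the groups. Where nothing was called, the gene of smallest p in each direction is given as a value only. List members may be named where they pass over all genes or over the list alone, and 15 genes chosen in advance are given in their main class whatever their result. Unnamed gene models, ribosomal protein genes and genes of the mitochondrial genome were counted but not named. Some genes that the rule takes are not reported here, and counts over the genes of the rule include them. A repeat of a gene across classes keeps the same rule. Genes named beside a count of 5 or fewer, or otherwise outside the rule, are said to be so in the text. Reads shared between paralogs, pseudogenes or overlapping genes could not be separated from these files.

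Alternatives fixed in advance were RLE normalization, no filter on low counts, DESeq2 1.42.0, a fit of only the 2 groups compared, the replicate number as a block and at least 1000 genes per nucleus. Further ones kept doublets, required under 1% mitochondrial UMIs, matched the clusters within a class across libraries, and left out each library in turn. After seeing the data 2 more were chosen: keeping nuclei with at least 1500 UMIs whatever the ambient test gave, and subtracting the expected free RNA per library and class. The share to subtract was estimated from markers of other cell types, and its profile from the barcodes with at most 100 UMIs.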

Results

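Nuclei from the frontal cerebral cortex of 8 C57BL/6 mice were profiled by single-nucleus RNA sequencing, with 1 library per mouse. The mice had received vehicle (n = 2), S-2MeGlu (n = 3) or R-4APA (n = 3) by intraperitoneal injection for 8 weeks, each compound at 10 mg/kg per day. The series design calls both compounds false neurotransmitters and asks what they do to each cell type. The libraries held 71892749 and 63663166 UMIs (unique molecular identifiers) for Vehicle 1 and 2, 61596240, 60164680 and 62789234 for S-2MeGlu 1 to 3, and 47495345, 66075308 and 66743666 for R-4APA 1 to 3. After filtering, 45512 nuclei remained, between 3727 (R-4APA 1) and 8433 (R-4APA 3) per library. Excitatory neurons, inhibitory neurons, astrocytes, oligodendrocytes, oligodendrocyte precursor cells (OPCs) and microglia made up 33306 of them, and counts were summed per mouse within each of these 6 classes. Expression is given as counts scaled to library size (CPM), as mean ± SD over the libraries of a group. Fold changes are log2 values ± SE. Free RNA, measured in barcodes with at most 100 UMIs, accounted for an estimated 8.44 ± 0.168% of the UMIs of excitatory nuclei in vehicle, 7.86 ± 1.23% under S-2MeGlu and 7.37 ± 1.25% under R-4APA, and for 28.0 ± 2.41%, 22.7 ± 0.801% and 26.5 ± 10.4% in microglia.

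S-2MeGlu was set against vehicle to find transcripts that this compound alters in cortical neurons. In inhibitory neurons Olfm3, which encodes the secreted protein olfactomedin 3 (ENSMUSG00000027965, chromosome 3, 114904078 to 115125722 in GRCm38), had the smallest p among genes with a higher level, at 213 ± 23.5 CPM against 127 ± 4.57 (n = 3 and 2). Its log2 fold change was 0.75 ± 0.13 with an edgeR adjusted p of 0.164. Without R-4APA 1 in the shared estimate of spread that adjusted p was 0.0121, within a range of 9.6e-09 to 1.0 over all alternatives. Nos1, which encodes neuronal nitric oxide synthase, had the smallest p among inhibitory genes with a lower level, at 51.6 ± 2.36 CPM against 77.4 ± 9.82. In excitatory neurons these places were held by Cldn5, a tight junction gene of endothelial cells, at 0.612 ± 0.298 CPM against 0.085 ± 0.12, and the X-linked gene Xlr3a at 0.189 ± 0.0751 CPM against 0.953 ± 0.386. Cldn5 passed only when adjusted over the list alone (0.0407, against an edgeR adjusted p of 1.0 over all genes). edgeR called 0 of 18524 genes in excitatory and 0 of 14267 in inhibitory neurons, and DESeq2 called 6 and 2. An unadjusted p under 0.05 was found for 416 and 459 genes, fewer than the 926 and 713 expected by chance. Leaving out S-2MeGlu 3 gave 2 calls in each class, leaving out R-4APA 1 gave 2 in inhibitory neurons, and leaving out R-4APA 2 or Vehicle 1 gave 1 there.

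In glia, S-2MeGlu was set against vehicle for the same question. Penk, which encodes the precursor of the enkephalin opioid peptides (ENSMUSG00000045573, chromosome 4, 4133531 to 4138819), had 20.9 ± 6.2 CPM against 80.3 ± 26 in microglia (n = 3 and 2), a log2 fold change of -1.87 ± 0.40 and an edgeR adjusted p of 0.0942. It passed when adjusted over the list alone (7.1e-05), and over all genes without Vehicle 2, R-4APA 1 or R-4APA 3, where the smallest adjusted p was 0.00826 in a range of 0.00826 to 1.0 over the alternatives. Penk is a striatal projection neuron transcript, and the neuronal marker lists that read free RNA in microglia were lower as well. In oligodendrocytes Abtb2 had 80.7 ± 4.78 CPM against 49.2 ± 9.32. In OPCs Fndc3b had 100.2 ± 11.7 CPM against 54.6 ± 4.74 and Myo1d, a myosin of oligodendrocytes, had 5.68 ± 0.584 CPM against 27.6 ± 20.4. Myo1d had an edgeR adjusted p of 0.358, and of 0.00613 without Vehicle 2 in a range of 0.00613 to 1.0. Astrocytes had Bdp1 at 72.8 ± 9.75 CPM against 41.4 ± 1.88 and Gas7 at 22.4 ± 2.56 CPM against 44.8 ± 0.931, and microglia had Tmcc1 at 307 ± 9.61 CPM against 201 ± 2.88. edgeR called 0 of 10609, 11880, 9608 and 7925 genes in astrocytes, oligodendrocytes, OPCs and microglia, and DESeq2 called 0 in each. An unadjusted p under 0.05 was found for 429, 509, 425 and 373, fewer than the 530, 594, 480 and 396 expected by chance, which does not show an absence of change. Calls appeared when 1 library was left out: 1 in astrocytes without Vehicle 1, 1 and 3 in oligodendrocytes without R-4APA 1 and Vehicle 2, 1 in OPCs without Vehicle 2, and 7, 1, 2 and 1 in microglia without R-4APA 1, R-4APA 3, Vehicle 1 and Vehicle 2.

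Among gene lists, the transcripts of the mitochondrial genome, which encode core subunits of the respiratory chain, were lower under S-2MeGlu than vehicle in all 6 classes. Their median log2 fold changes were -0.59, -0.60, -0.47, -0.46, -0.62 and -0.53 in excitatory neurons, inhibitory neurons, astrocytes, oligodendrocytes, OPCs and microglia. edgeR called 0 members over all genes. Per class 373 to 509 genes had an unadjusted p under 0.05, fewer than expected by chance. DESeq2 called 6 and 2 genes in the neurons and 0 in the glia. edgeR called 11, 8, 0, 4, 4 and 5 of 13, 13, 12, 13, 10 and 11 when adjusted over the list alone. In excitatory nuclei they took 0.0578 ± 0.0046% of UMIs under S-2MeGlu and 0.0901 ± 0.0042% in vehicle, less than the free RNA estimate in both groups, and in free RNA itself 1.65 ± 0.488% and 2.45 ± 0.332%. Immediate early genes, which neuronal activity induces, had a median of 0.68 over 25 members in excitatory neurons (camera adjusted p = 3.9e-06). The call was lost at adjusted p = 0.864 with an estimated correlation, and edgeR called 0 members over all genes and 0 adjusted over the list alone. That list mean, relative to the vehicle mean, was 0.49 in Vehicle 1 and -0.49 in Vehicle 2, and without Vehicle 2 the camera adjusted p was 0.906 (range over the alternatives 2.6e-12 to 0.906). Cholesterol synthesis genes had medians of 0.15 in excitatory neurons and 0.37 in astrocytes (camera adjusted p = 0.000105 and 6.7e-05). They missed at adjusted p = 0.864 and 0.994 with an estimated correlation, and also without Vehicle 2 (0.217; range 2.9e-06 to 0.217) and without Vehicle 1 (0.403; range 4.2e-07 to 0.403). In OPCs they were lower, with a median of -0.28 (camera adjusted p = 0.0453, range 0.0088 to 0.818; adjusted p = 0.907 with an estimated correlation). The camera adjusted p of the mitochondrial list was 3.6e-17, 7.0e-11, 1.4e-05, 6.6e-08, 2.2e-06 and 0.000159. It missed in each class, at adjusted p = 0.864, 0.682, 0.994, 0.588, 0.907 and 0.531 with an estimated correlation. Leave-one-out fits lost only the astrocyte call, without Vehicle 1 (0.0546; range 4.2e-07 to 0.0546), and subtraction of free RNA was not tested. Markers that check the dissection and free RNA were lower as well. Striatal projection neuron markers had medians of -0.54, -0.23, -0.71, -0.16 and -1.06 in the classes other than astrocytes, at adjusted p = 0.864, 0.854, 0.588, 0.907 and 0.531 with an estimated correlation. Excitatory neuron markers had -0.38, -0.29, -0.31 and -0.38 in inhibitory neurons, astrocytes, oligodendrocytes and microglia, at adjusted p = 0.854, 0.994, 0.659 and 0.536 with an estimated correlation. Neuropeptides had -0.37, -0.58, -0.43, -0.53 and -0.62 in the classes other than inhibitory neurons, at adjusted p = 0.864, 0.994, 0.659, 0.907 and 0.531 with an estimated correlation. In excitatory neurons the medians of the neuropeptides and of the striatal markers turned to 0.04 and 0.13 with free RNA subtracted. Of these camera calls only those of striatal markers in microglia and of excitatory markers in inhibitory neurons and microglia held in all 8 leave-one-out fits. Vehicle 1, Vehicle 2, S-2MeGlu 1, S-2MeGlu 2 or S-2MeGlu 3 was the library without which others were lost, with a largest camera adjusted p of 0.374, 0.205 and 0.605 in the 3 lists. Of 198 pairs of list and class 47 passed with camera, 4 higher and 43 lower, and 0 passed with an estimated correlation.

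R-4APA was set against vehicle with the same question. In excitatory neurons Serinc1, a gene for a membrane protein that helps to build serine into lipids (ENSMUSG00000019877, chromosome 10, 57515774 to 57532530), fell under R-4APA to 118 ± 10.7 CPM against 188 ± 6.71 (n = 3 and 2). Atp6v0c, which encodes the proton pore of the vacuolar ATPase that fills synaptic vesicles and acidifies lysosomes (ENSMUSG00000024121, chromosome 17, 24163866 to 24169702), fell to 122 ± 13.9 CPM against 204 in both vehicle libraries. Ndufa13, a subunit of respiratory complex I, fell to 41.3 ± 2.65 CPM against 72.4 ± 9.97. The log2 fold changes of Serinc1, Atp6v0c and Ndufa13 were -0.67 ± 0.08, -0.75 ± 0.09 and -0.81 ± 0.10, with an edgeR adjusted p of 0.0131 for each. Chgb, for the secretory granule protein chromogranin B, fell by 0.52 on the log2 scale, as did Npy (neuropeptide Y) by 0.96 and the synaptic vesicle GTPase gene Rab3a by 0.73 (edgeR adjusted p = 0.0153, 0.0433 and 0.0465). Aste1, Dnase2a and the organic cation transporter gene Slc22a2 rose by 0.37 ± 0.08, 0.55 ± 0.12 and 2.68 ± 0.59 (edgeR adjusted p = 0.0385, 0.0446 and 0.050), Slc22a2 from 0.219 ± 0.31 to 1.83 ± 0.402 CPM. Slc22a2 had 0 CPM in Vehicle 1, and its log2 fold change ranged from 2.05 to 8.03 over the leave-one-out fits. In all, 251 genes fell and 12 rose of 18524, and the libraries of all 263 did not overlap between groups, as for 30.7% of all genes against 20% by chance. Leaving out Vehicle 1, R-4APA 1 or R-4APA 3 gave 0 calls, S-2MeGlu 2 gave 53, S-2MeGlu 1 gave 165, R-4APA 2 gave 168, S-2MeGlu 3 gave 419 and Vehicle 2 gave 474. Of the 9 genes named, 0 passed without Vehicle 1, R-4APA 1 or R-4APA 3, 4 without S-2MeGlu 1, 5 without S-2MeGlu 2 or R-4APA 2, and 7 without Vehicle 2. Subtracting free RNA left 2 of the 263 with their call, and 184 of the 244 still tested with their sign. Serinc1 then stood at -0.74 (edgeR adjusted p = 0.0456, in a range of 1.4e-07 to 0.161 over the alternatives), Atp6v0c at -0.76 and Ndufa13 at 0.24.

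In inhibitory neurons Ndufa4, a cytochrome c oxidase subunit (ENSMUSG00000029632, chromosome 6, 11900292 to 11907497), fell under R-4APA to 75.5 ± 6.38 CPM against 143 ± 25 (n = 3 and 2). The chaperone gene Ppia (cyclophilin A) fell to 94.5 ± 6.34 CPM against 159.6 ± 14.7 and Ndufc2, another complex I subunit, to 45.3 ± 0.418 CPM against 83.5 ± 10.7. Their log2 fold changes were -0.91 ± 0.11, -0.75 ± 0.10 and -0.88 ± 0.12 (edgeR adjusted p = 0.000698, 0.000994 and 0.00154). Slc32a1, which encodes the transporter that loads GABA into vesicles (ENSMUSG00000037771, chromosome 2, 158610767 to 158615748), fell by 0.61 to 98.2 ± 13.8 CPM against 149 ± 19.2 (edgeR adjusted p = 0.0153). Tac1, the substance P precursor, fell by 0.93 and Hsp90aa1, a heat shock chaperone, by 0.77 (edgeR adjusted p = 0.0106 and 0.0307; Hsp90aa1 ranged from -1.03 to -0.46 when 1 library was left out), and Olfm3 rose to 189 ± 34.1 CPM against 127 ± 4.57 (edgeR adjusted p = 0.045). In all, 112 genes fell and 7 rose of 14267, with libraries of all 119 not overlapping (28.8% of all genes against 20% by chance). The count was 0 without Vehicle 1, 30 without R-4APA 1, 31 without R-4APA 3, 72 without R-4APA 2, 223 without S-2MeGlu 3 and 226 without Vehicle 2. Of the 7 genes named, 0 passed without Vehicle 1, 4 without R-4APA 3, 5 without R-4APA 1, R-4APA 2 or Vehicle 2, and 6 without S-2MeGlu 1 or S-2MeGlu 2. With free RNA subtracted edgeR called 0 genes, and 78 of 104 calls tested kept their sign, Slc32a1 at -0.64.

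In astrocytes Cck, the cholecystokinin precursor (ENSMUSG00000032532, chromosome 9, 121489824 to 121495694), fell under R-4APA to 79.3 ± 28.1 CPM against 202 ± 3.21 (n = 3 and 2). Ppia fell to 169 ± 39.4 CPM against 332 ± 15. Their log2 fold changes were -1.33 ± 0.21 and -0.96 ± 0.17 (edgeR adjusted p = 0.0154 and 0.0241). Cck is a neuronal transcript, and the list of excitatory neuron markers, which reads free RNA in astrocytes, had a median of -0.45. The heat shock genes Hspa8 and Hsp90aa1 fell by 0.94 and 1.01 (edgeR adjusted p = 0.025 and 0.0263), Hsp90aa1 within -1.26 to -0.69 over the leave-one-out fits. In OPCs Hsp90aa1 fell by 1.09 to 133 ± 17.4 CPM against 284 ± 100.3, and the tubulin genes Tubb4a and Tubb4b by 1.33 and 1.73 (edgeR adjusted p = 0.00485, 0.0119 and 0.0119). Hsp90aa1 lay within -1.41 to -0.68 there when 1 library was left out. In all, 31 of 10609 genes fell in astrocytes and 10 of 9608 in OPCs, all without overlap between groups (25.3% and 24.1% of all genes did not overlap, against 20% by chance). DESeq2 called 32 falling genes in astrocytes and 1 in OPCs. edgeR called 0 rising genes in either class, DESeq2 also called 0, and 912 and 809 genes had an unadjusted p under 0.05 in either direction. Astrocytes had 0 calls without Vehicle 1 or S-2MeGlu 2, 1 without R-4APA 1 or R-4APA 3, 14 without S-2MeGlu 1, 17 without R-4APA 2 and 19 without S-2MeGlu 3. OPCs had 0 without Vehicle 1 or R-4APA 1, 18 without R-4APA 3 and 72 without Vehicle 2. Of the 5 astrocyte genes that the naming rule takes, 0 passed without Vehicle 1 or S-2MeGlu 2 and 1 without R-4APA 1 or R-4APA 3, and of the 3 OPC genes 0 passed without Vehicle 1 or R-4APA 1 and 1 without R-4APA 2. With free RNA subtracted edgeR called 0 genes in both classes, and 25 of 27 and 8 of 8 calls tested kept their sign. The lost calls do not show that free RNA carried these changes.

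Oligodendrocytes under R-4APA had lower Chchd2, a regulator of mitochondrial respiration, at 131 ± 26.4 CPM against 294 ± 51 (n = 3 and 2). Ndufa4 fell to 178 ± 30.4 CPM against 339 ± 51.1 and Hint1, a nucleotide hydrolase, to 88.3 ± 7.14 CPM against 165 ± 18.7. The log2 fold changes of Chchd2, Ndufa4 and Hint1 were -1.15 ± 0.17, -0.93 ± 0.15 and -0.90 ± 0.14, with an edgeR adjusted p of 0.00672 for each. The chaperone genes Hspa8, Hsp90aa1 and Hspa5 fell by 0.91, 0.83 and 0.70 (edgeR adjusted p = 0.0133, 0.0133 and 0.0164), Hsp90aa1 within -1.12 to -0.45 over the leave-one-out fits. Abtb2 rose to 79 ± 1.61 CPM against 49.2 ± 9.32 and the noncoding RNA gene Snhg9 to 70.9 ± 13.5 CPM against 43.4 ± 4.34 (edgeR adjusted p = 0.0291 and 0.0295). In all, 205 genes fell and 6 rose of 11880, with libraries of all 211 not overlapping (27.9% of all genes against 20% by chance). The count was 0 without Vehicle 1 and 133 without R-4APA 3. Of the 9 genes that the naming rule takes, 0 passed without Vehicle 1, 3 without R-4APA 3, 5 without R-4APA 2, and 7 without S-2MeGlu 2 or Vehicle 2. With free RNA subtracted edgeR called 0 genes, 111 of 191 calls tested kept their sign with a median that went from -0.78 to -0.15, Chchd2 stood at -0.15 and Hint1 at 2.44, a sign opposite to its fall.

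Microglia under R-4APA had lower Ubb, a ubiquitin gene, at 306 ± 58.5 CPM against 628 ± 137, and lower Mif, which encodes a cytokine that holds macrophages in place (ENSMUSG00000033307, chromosome 10, 75859353 to 75860240), at 72.5 ± 29.7 CPM against 206 ± 17.8 (n = 3 and 2). Cmss1 fell to 8968 ± 2149 CPM against 16522 ± 1442. The log2 fold changes of Ubb, Mif and Cmss1 were -1.02 ± 0.16, -1.45 ± 0.24 and -0.88 ± 0.15 (edgeR adjusted p = 0.000156, 0.000175 and 0.000175). Mif and Cmss1 passed in all 8 leave-one-out fits, with a largest edgeR adjusted p of 0.00901 and 0.0146. Subtracting free RNA put Cmss1 at -1.09, where it missed (edgeR adjusted p = 0.53, range 6.7e-12 to 0.53). Hk2, for the glycolytic enzyme hexokinase 2, rose to 988 ± 136 CPM against 650.4 ± 0.519 (log2 fold change 0.60 ± 0.16, edgeR adjusted p = 0.038). The call of Hk2 was lost without R-4APA 3, Vehicle 1 or Vehicle 2 (0.126, 0.281 and 0.110; range over the alternatives 0.00781 to 0.687). It was also lost with clusters matched across libraries, at a log2 fold change of 0.47 (adjusted p = 0.273). Hk2 is a leading gene of microglial cluster 18, which held 21, 114 and 354 nuclei in R-4APA 1 to 3 and 109 and 128 in vehicle, where the other microglial cluster held 158, 173 and 83, and 147 and 187. Of the list of genes that mark disease-associated microglia, 2 of 15 members fell over all genes and 6 adjusted over the list alone, with a median of -0.43 (camera adjusted p = 0.000618; adjusted p = 0.334 with an estimated correlation) and of -0.50 after free RNA was subtracted. The same list was lower in excitatory and inhibitory neurons, with medians of -0.33 and -0.37 (camera adjusted p = 0.000647 and 0.00126; range 0.000142 to 0.162 and 7.6e-05 to 0.0149; adjusted p = 0.415 and 0.499 with an estimated correlation), and of -0.10 and -0.27 with free RNA subtracted. In all, 105 genes fell and 2 rose of 7925, and libraries did not overlap for 106 of the 107 (27.0% of all genes against 20% by chance). The count was 8 without Vehicle 1, 164 without Vehicle 2 and 174 without R-4APA 3. Of the 4 genes named, 2 passed without Vehicle 1 and 3 without R-4APA 3 or Vehicle 2. With free RNA subtracted 8 genes fell, 7 of them among the 107, and 76 of 77 calls tested kept their sign.

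Across classes, the lists of the nuclear-encoded respiratory chain and of the cytosolic ribosome had lower medians under R-4APA. Of 50 oxidative phosphorylation genes, 20, 13, 4, 25, 1 and 15 fell in excitatory neurons, inhibitory neurons, astrocytes, oligodendrocytes, OPCs and microglia over all genes, and 42, 33, 29, 42, 22 and 31 adjusted over the list alone. Ndufa13, Ndufa4 and Ndufc2 are among them. Their median log2 fold changes were -0.51, -0.43, -0.53, -0.69, -0.62 and -0.66 (camera adjusted p = 1.4e-30, 1.8e-21, 2.4e-16, 8.4e-27, 7.7e-17 and 1.7e-20). None passed when camera estimated the correlation, at adjusted p = 0.415, 0.451, 0.592, 0.41, 0.459 and 0.334 with an estimated correlation. Of 54 ribosomal protein genes, 38, 23, 6, 30, 2 and 17 fell over all genes and 49, 49, 41, 46, 28 and 39 adjusted over the list alone. The medians were -0.61, -0.63, -0.57, -0.61, -0.56 and -0.62, at adjusted p = 0.415, 0.451, 0.592, 0.41, 0.459 and 0.334 with an estimated correlation. Neither list lost a camera call in any leave-one-out fit. Free RNA was also lowest in these transcripts under R-4APA: oxidative phosphorylation transcripts made up 2.64 ± 0.608% of it in vehicle, 2.68 ± 0.31% under S-2MeGlu and 1.7 ± 0.221% under R-4APA. Ribosomal protein transcripts made up 3.78 ± 0.711%, 4.1 ± 0.624% and 2.71 ± 0.311%. In excitatory nuclei oxidative phosphorylation transcripts took 0.283 ± 0.0416%, 0.275 ± 0.0104% and 0.197 ± 0.0124% of UMIs. Of these 0.222%, 0.209% and 0.123% were expected from free RNA. After free RNA was subtracted, the medians of the oxidative phosphorylation list were 0.11, 0.19, 0.16, 0.41, 0.03 and -0.33, so that its direction held only in microglia, and those of the ribosomal list 0.06, 0.08, -0.32, 0.46, -0.21 and -0.46. The subtraction can take too much. For mitochondrially encoded transcripts in vehicle excitatory nuclei it expected 0.206%, and 0.0901% was observed. The ribosomal share expected was above that observed in excitatory nuclei of S-2MeGlu 1 (0.356 against 0.351%) and in inhibitory nuclei of Vehicle 1 (0.480 against 0.457%) and R-4APA 3 (0.315 against 0.298%). The turned medians therefore do not show a rise.

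The lists of chaperone and of neuropeptide genes had lower medians under R-4APA in the same 6 classes. The heat shock and protein folding list had medians of -0.36, -0.32, -0.37, -0.30, -0.34 and -0.43. Hsp90aa1 and Hspa8 belong to it, and 0, 1, 2, 3, 1 and 3 of 23, 22, 22, 24, 20 and 18 members fell over all genes, 10, 8, 6, 11, 5 and 6 adjusted over the list alone. In excitatory neurons, where edgeR called 0 heat shock members, 2302 of all genes had an unadjusted p under 0.05 and DESeq2 called 486 genes. With free RNA subtracted these medians were -0.13, -0.17, -0.37, -0.31, -0.35 and -0.32. The camera adjusted p of the list was 1.3e-05, 2.0e-05, 5.4e-05, 0.000101, 0.00631 and 0.000589. It missed at adjusted p = 0.561, 0.499, 0.592, 0.472, 0.678 and 0.334 with an estimated correlation. In each class the call was lost without Vehicle 1, where the camera adjusted p was 0.164, 0.113, 0.0635, 0.298, 0.96 and 0.143, and in OPCs also without R-4APA 3. The smallest over the alternatives was 2.6e-09, 1.8e-08, 1.2e-05, 4.6e-09, 6.8e-07 and 0.000106. The neuropeptide list had medians of -0.60, -0.45, -0.80, -0.64, -0.70 and -0.61, at adjusted p = 0.561, 0.451, 0.592, 0.472, 0.459 and 0.536 with an estimated correlation. It had 2, 1, 1, 1, 0 and 0 members that fell of 17, 15, 9, 11, 7 and 9, with 6, 5, 4, 3, 4 and 5 adjusted over the list alone. Npy in excitatory neurons, Tac1 in inhibitory neurons and Cck in astrocytes were among those that fell. Cell type markers were lower too. Excitatory neuron markers had medians of -0.12, -0.35, -0.45, -0.63, -0.36 and -0.35 in the 6 classes, at adjusted p = 0.561, 0.499, 0.768, 0.472, 0.678 and 0.613 with an estimated correlation. Myelin genes had -0.46, -0.50, -0.42, -0.84 and -0.36 in the 5 classes other than oligodendrocytes, at adjusted p = 0.561, 0.571, 0.768, 0.459 and 0.613 with an estimated correlation. Subtracting free RNA turned the myelin medians to 0.15, 0.29 and 0.31 in excitatory neurons, inhibitory neurons and astrocytes. The lowest subtracted median of that list over the 6 classes was -0.93. In both neuron classes the share subtracted was itself estimated from oligodendrocyte markers, so the turn there cannot show where the signal came from. Without Vehicle 1 or R-4APA 1 myelin calls were lost, at camera adjusted p up to 0.946, and the astrocyte median was 0.11 without Vehicle 1. Excitatory marker calls were lost without Vehicle 1, R-4APA 1 or R-4APA 3 in every class but oligodendrocytes, at up to 0.265. Of 391 genes that fell in at least 1 class, 178 fell in 2 or more and 2, Ppia and Ubb, in all 6. Excitatory and inhibitory neurons shared 86 fallen genes against 1.98 expected from independent lists, and excitatory neurons and oligodendrocytes shared 106 against 4.39, although all classes share the same vehicle mice and free RNA. Of 198 pairs of list and class 54 passed with camera, 4 higher and 50 lower, 5 passed with fry, and 0 with an estimated correlation.

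**Figure D1:**
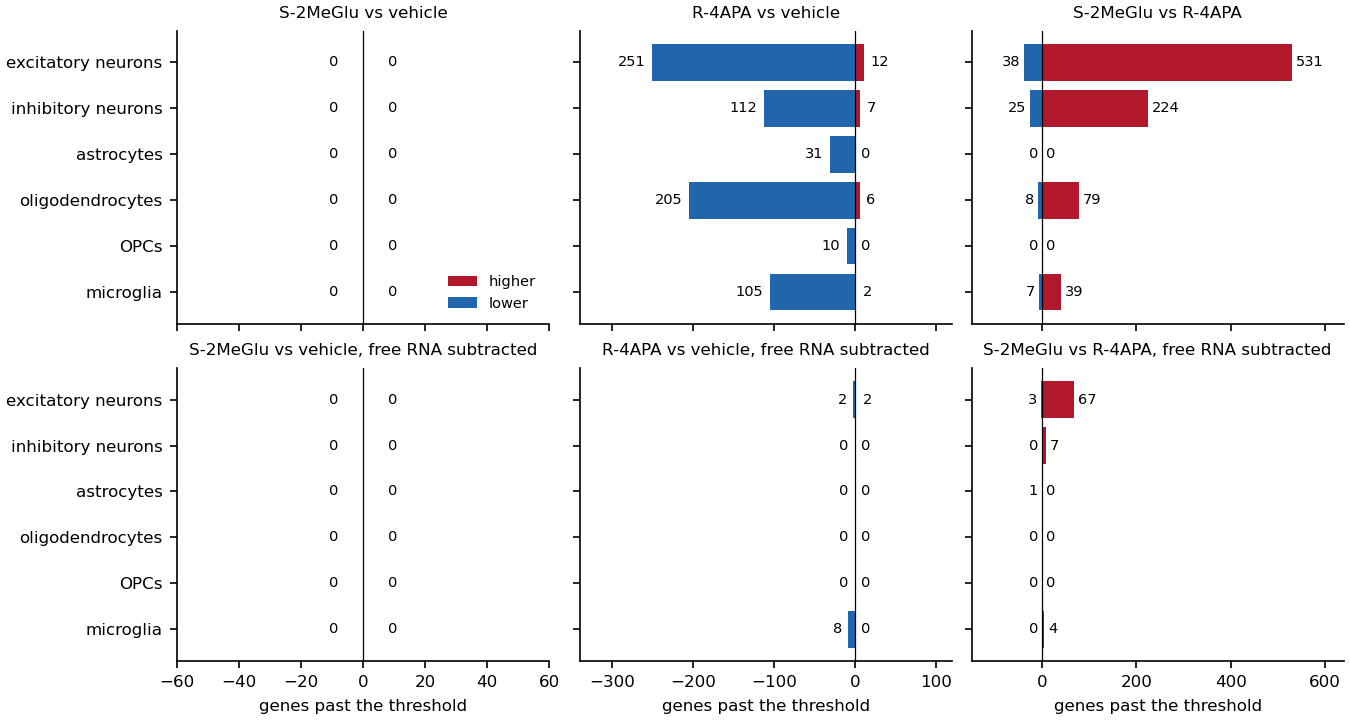
Genes past an edgeR adjusted p of 0.05 per class (red bars higher, blue bars lower in the group named first), for the 3 comparisons, before (top) and after (bottom) free RNA was subtracted. In excitatory neurons 251 genes were lower under R-4APA than vehicle before subtraction and 2 after it, and 531 and 67 were higher under S-2MeGlu than R-4APA.

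**Figure D2:**
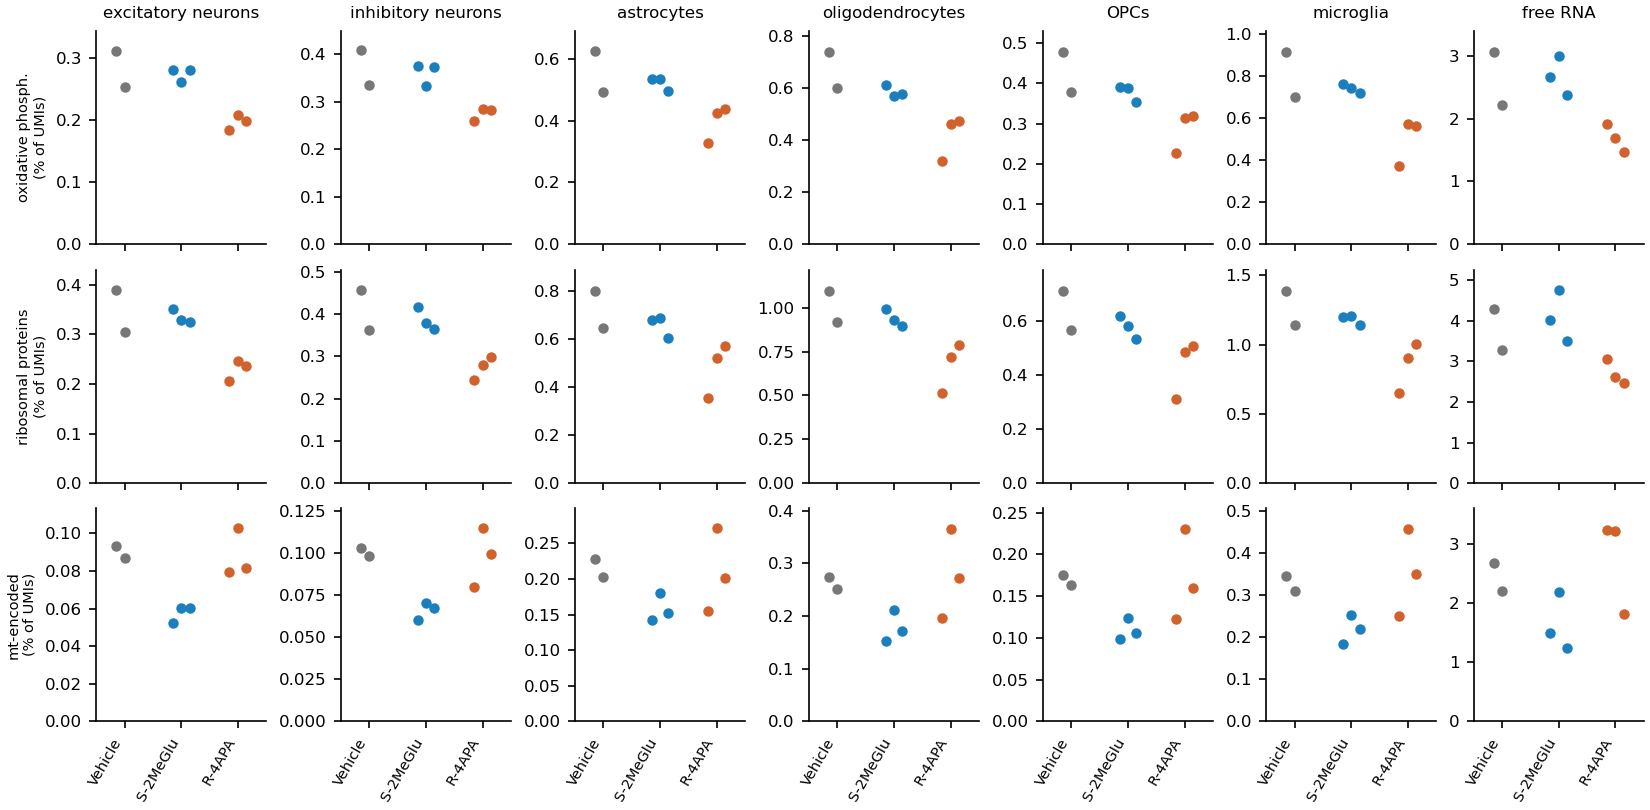
Share of UMIs (percent, 1 point per library) taken by the nuclear-encoded oxidative phosphorylation, ribosomal protein and mitochondrially encoded lists in each class and in free RNA. The 3 R-4APA libraries lie below both vehicle libraries for the oxidative phosphorylation list in all 6 classes and in free RNA.

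The compounds were also compared at the same dose and duration. Rises and falls in this comparison are S-2MeGlu relative to R-4APA, not vehicle. The tissue taken differed as well: left-out cluster 31 held at least 1.07% of nuclei under S-2MeGlu and at most 0.0268% under R-4APA. Its effect on the calls was not tested. In excitatory neurons Arl6ip1, a gene that shapes endoplasmic reticulum tubules (ENSMUSG00000030654, chromosome 7, 118118891 to 118129662), was higher under S-2MeGlu at 90.7 ± 7.97 CPM against 54 ± 3.81 (n = 3 and 3). Atp6v0c was also higher at 211 ± 16.6 CPM against 122 ± 13.9, as was the ATP synthase gene Atp5f1 at 80.3 ± 7.35 CPM against 43.8 ± 2.47. Their log2 fold changes were 0.75 ± 0.08, 0.80 ± 0.09 and 0.88 ± 0.09, with an edgeR adjusted p of 0.00252 for each. Chgb and Syt4, a synaptotagmin of dense core vesicles, rose by 0.49 ± 0.07 and 0.52 ± 0.08 (edgeR adjusted p = 0.00478 and 0.00654). Other list members that rose were Hsp90aa1 by 1.04, the endoplasmic reticulum chaperone gene Calr by 0.75, Cck by 0.54, the aminotransferase Got1 by 0.47, the extrasynaptic GABA-A subunit Gabrd by 0.40 and the potassium channel Kcna2 by 0.38 (edgeR adjusted p from 0.0171 to 0.0396). Cep112 fell by 0.67, Adam18 by 0.71 and Macrod2os2, an antisense gene whose reads are uncertain because no source states that counting used strand, by 0.59 (edgeR adjusted p = 0.0185, 0.0234 and 0.0233). In all, 531 genes were higher and 38 lower under S-2MeGlu, with libraries of all 569 not overlapping (21.2% of all genes against 10% by chance). Calls numbered 77 without R-4APA 3, 252 without R-4APA 1, 280 without S-2MeGlu 1, 363 without R-4APA 2 and 374 without S-2MeGlu 2. Of 16 genes taken under the naming rule, Slc17a7 included, 5 passed without R-4APA 3, 8 without R-4APA 1 or S-2MeGlu 1, 10 without R-4APA 2 or S-2MeGlu 3, 11 without S-2MeGlu 2, and 15 without either vehicle. Arl6ip1, Atp6v0c, Atp5f1, Chgb and Syt4 passed in all 8 leave-one-out fits. Subtracting free RNA left 67 of 532 calls tested with their call and 460 with their sign, at a median of 0.44 after 0.54 before, Arl6ip1 at 0.80, Atp6v0c at 0.94, Chgb at 0.51 and Syt4 at 0.58. Atp5f1 stood at 0.79 and missed (edgeR adjusted p = 0.0702, range 2.0e-12 to 0.0702).

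In inhibitory neurons Slc32a1 was higher under S-2MeGlu at 166 ± 14.7 CPM against 98.2 ± 13.8, and Vip, the vasoactive intestinal peptide of a class of interneurons, at 428 ± 40.8 CPM against 245 ± 36.7 (n = 3 and 3). Their log2 fold changes were 0.76 ± 0.11 and 0.81 ± 0.12 (edgeR adjusted p = 0.000864 and 0.00333). Ppia, Ndufa4 and AY036118 had the smallest p, with rises of 0.77 ± 0.09, 0.85 ± 0.10 and 0.65 ± 0.08 and an edgeR adjusted p of 0.000158 for each. The peptide precursors Crh, Tac2, Tac1 and Cck and the granule protein gene Scg2 rose by 0.94, 0.84, 0.65, 0.52 and 0.53 (edgeR adjusted p = 0.0359, 0.0404, 0.0375, 0.0208 and 0.0165). The chaperone genes Hsp90aa1 and Hspa8 rose by 0.88 and 0.88 (edgeR adjusted p = 0.00563 and 0.0431). Snhg9, the actin nucleator gene Cobl and the transcription factor gene Lmo3 fell by 0.79, 0.73 and 0.48 (edgeR adjusted p = 0.00985, 0.0189 and 0.026). In all, 224 genes were higher and 25 lower, with libraries of all 249 not overlapping (16.7% of all genes against 10% by chance). The count was 54 without S-2MeGlu 1, 60 without R-4APA 3, 137 without R-4APA 1, 142 without R-4APA 2 and 378 without S-2MeGlu 3. Of 16 genes named here, Gad2 included, 5 passed without R-4APA 3, 7 without R-4APA 2 or S-2MeGlu 1, 10 without R-4APA 1, 12 without S-2MeGlu 2, 14 without S-2MeGlu 3 and 15 without either vehicle. Slc32a1, Vip, Ppia, Ndufa4 and AY036118 passed in all 8 leave-one-out fits. Of the calls tested after free RNA was subtracted, 7 of 231 kept their call and 206 their sign, with a median log2 fold change of 0.59 before and 0.57 after it. Slc32a1 stood at 0.81 (edgeR adjusted p = 0.0272, in a range of 8.2e-13 to 0.0272) and Vip at 0.82 (0.0272, in a range of 2.6e-18 to 0.153). Ppia, Ndufa4 and AY036118 missed after it, at 0.78, 0.90 and 0.81 (edgeR adjusted p = 0.758, 0.669 and 0.777; range 7.3e-13 to 0.758, 1.6e-14 to 0.669 and 3.0e-16 to 0.777).

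In oligodendrocytes Sox10, the transcription factor gene that maintains the lineage, was lower under S-2MeGlu by 0.54 (edgeR adjusted p = 0.037). It had 374 ± 27.5 CPM against 545 ± 51.6 under R-4APA (n = 3 and 3), and 391 and 381 in Vehicle 1 and 2. Chchd2, Hint1 and the translationally controlled tumour protein gene Tpt1 rose by 1.06 ± 0.15, 0.88 ± 0.13 and 0.85 ± 0.13 (edgeR adjusted p = 0.00493 for each). Hsp90aa1, Jund and the channel gene Hcn2 rose by 0.94, 0.75 and 0.65 (edgeR adjusted p = 0.011, 0.0215 and 0.0473), while Snhg9 and Trank1 fell by 1.04 and 1.25 (0.011 and 0.0408). In all, 79 genes were higher and 8 lower, with libraries of all 87 not overlapping (14.2% of all genes against 10% by chance). The count was 0 without S-2MeGlu 1, S-2MeGlu 2 or R-4APA 3, 15 without S-2MeGlu 3, 24 without R-4APA 2 and 148 without R-4APA 1. Of the 9 genes named, 0 passed without S-2MeGlu 1, S-2MeGlu 2 or R-4APA 3, 4 without S-2MeGlu 3 and 5 without R-4APA 2. After free RNA was subtracted edgeR called 0 genes, and 54 of 76 calls tested kept their sign, with a median of 0.69 before and 0.31 after it. Ppia, Hint1, Tpt1 and Hspa8 have near-identical processed copies elsewhere in the genome, so shared reads make their counts uncertain.

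In microglia Tmsb4x, an actin-binding peptide gene abundant in these cells, was higher under S-2MeGlu. It had 1967 ± 98.4 CPM against 1261 ± 108 (n = 3 and 3). Ubb and Uqcrh, a complex III subunit, rose with it, the 3 by 0.64 ± 0.13, 0.92 ± 0.15 and 1.04 ± 0.20 (edgeR adjusted p = 0.00355, 0.000509 and 0.00355). The neuronal genes Cadm2 and Cacna1e fell by 0.98 and 1.89, and Tmem179b by 1.19 (edgeR adjusted p = 0.0256, 0.0287 and 0.0472). In all, 39 genes were higher and 7 lower, with libraries of 44 of the 46 not overlapping (12.9% of all genes against 10% by chance). The count was 1 without S-2MeGlu 1, 10 without S-2MeGlu 2, 73 and 79 without Vehicle 2 and Vehicle 1, 75 without R-4APA 3 and 85 without R-4APA 1. Of the 6 genes named, 1 passed without S-2MeGlu 1, 3 without S-2MeGlu 2, R-4APA 2 or R-4APA 3, and 5 without S-2MeGlu 3. Subtracting free RNA left 3 of the calls past the threshold and 31 of 31 tested with their sign, while the median of the calls went from 0.84 to 1.60. In astrocytes Ppia (log2 fold change 0.78 ± 0.15) and the kainate receptor gene Grik1 (-1.11 ± 0.22) had the smallest p, both with an edgeR adjusted p of 0.0612, and Grik1 passed when adjusted over the list alone (0.000493). In OPCs these were Ubb (0.83 ± 0.16, edgeR adjusted p = 0.0529) and Myo1d (-2.20 ± 0.50, 0.16). edgeR called 0 genes in astrocytes and 0 in OPCs, with 850 and 624 at an unadjusted p under 0.05, and DESeq2 called 15 and 0. Astrocytes had 2 calls without R-4APA 2, Ppia among them, and 13 without S-2MeGlu 3, Grik1 among them, and OPCs had 2 without R-4APA 2 and 10 without Vehicle 1 or Vehicle 2, Ubb and Myo1d among these.

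Gene lists were compared as well. The median of oxidative phosphorylation transcripts was higher under S-2MeGlu than R-4APA in all 6 classes, with 32, 17, 0, 9, 0 and 10 of 50 members rising over all genes and 44, 36, 24, 32, 7 and 22 adjusted over the list alone. The medians were 0.48, 0.41, 0.41, 0.51, 0.37 and 0.52, at adjusted p = 0.531, 0.299, 0.822, 0.398, 0.594 and 0.678 with an estimated correlation. Of the 54 ribosomal protein genes 42, 30, 0, 14, 0 and 6 rose over all genes and 50, 48, 33, 46, 5 and 34 adjusted over the list alone. Their medians were 0.57, 0.55, 0.50, 0.54, 0.45 and 0.50, at adjusted p = 0.531, 0.299, 0.822, 0.398, 0.594 and 0.678 with an estimated correlation. The mitochondrially encoded transcripts went the other way, with 6, 2, 0, 3, 0 and 3 of 13, 13, 12, 13, 10 and 11 falling over all genes and 12, 10, 0, 12, 9 and 11 adjusted over the list alone. Those medians were -0.56, -0.51, -0.45, -0.76, -0.71 and -0.68, at adjusted p = 0.531, 0.435, 0.872, 0.398, 0.594 and 0.678 with an estimated correlation. In astrocytes and OPCs, where edgeR called 0 members of the 3 lists, 850 and 624 of all genes had an unadjusted p under 0.05 and DESeq2 called 15 and 0 genes. With free RNA subtracted the mitochondrial list was not tested, and the oxidative phosphorylation medians were -0.03, 0.06, -0.06, -0.22, -0.17 and 0.58. Their direction held in inhibitory neurons and microglia. The ribosomal medians were then -0.23, -0.03, 0.09, -0.14, -0.04 and 0.56. The neuropeptide list of inhibitory neurons had 6 of 15 members rising, 11 adjusted over the list alone, and a median of 0.61 (0.70 with free RNA subtracted). Its camera adjusted p was 5.3e-10 (adjusted p = 0.299 with an estimated correlation). In excitatory neurons 2 of 17 neuropeptide genes rose, 3 adjusted over the list alone, with a median of 0.38. The camera adjusted p was 0.00357, and 0.448 without R-4APA 1 in a range of 1.2e-05 to 0.448 (adjusted p = 0.72 with an estimated correlation). The heat shock list had 3 of 23 members rising in excitatory and 6 of 22 in inhibitory neurons, 14 and 11 adjusted over the list alone. Its medians were 0.47 and 0.50 (0.38 and 0.42 with free RNA subtracted; adjusted p = 0.531 and 0.435 with an estimated correlation). In inhibitory neurons the list for GABA synthesis, transport and breakdown had 2 of 8 members rising, Slc32a1 and Gad2, and 4 adjusted over the list alone. Its median was 0.19, and 0.27 with free RNA subtracted (camera adjusted p = 0.00182; adjusted p = 0.435 with an estimated correlation). Markers for dissection and free RNA differed too. Excitatory neuron markers had medians of 0.13 and 0.25 in excitatory neurons and oligodendrocytes (camera adjusted p = 0.00357 and 0.0147, range 0.00255 to 0.0351 and 0.000353 to 0.997; adjusted p = 0.531 and 0.726 with an estimated correlation). Striatal projection neuron markers had -0.54 and -0.39 in oligodendrocytes and OPCs (camera adjusted p = 0.0158 and 0.0452, range 5.4e-05 to 0.262 and 0.00528 to 0.634; adjusted p = 0.56 and 0.594 with an estimated correlation). The oligodendrocyte calls were lost without S-2MeGlu 3 for both lists, without R-4APA 1 for the excitatory markers and without R-4APA 2 or R-4APA 3 for the striatal ones. The OPC call was lost without any of Vehicle 1, Vehicle 2, S-2MeGlu 2, S-2MeGlu 3, R-4APA 2 and R-4APA 3. Of 198 pairs of list and class 45 passed with camera, 33 higher and 12 lower, 5 passed with fry, and 0 with an estimated correlation.

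**Figure D3:**
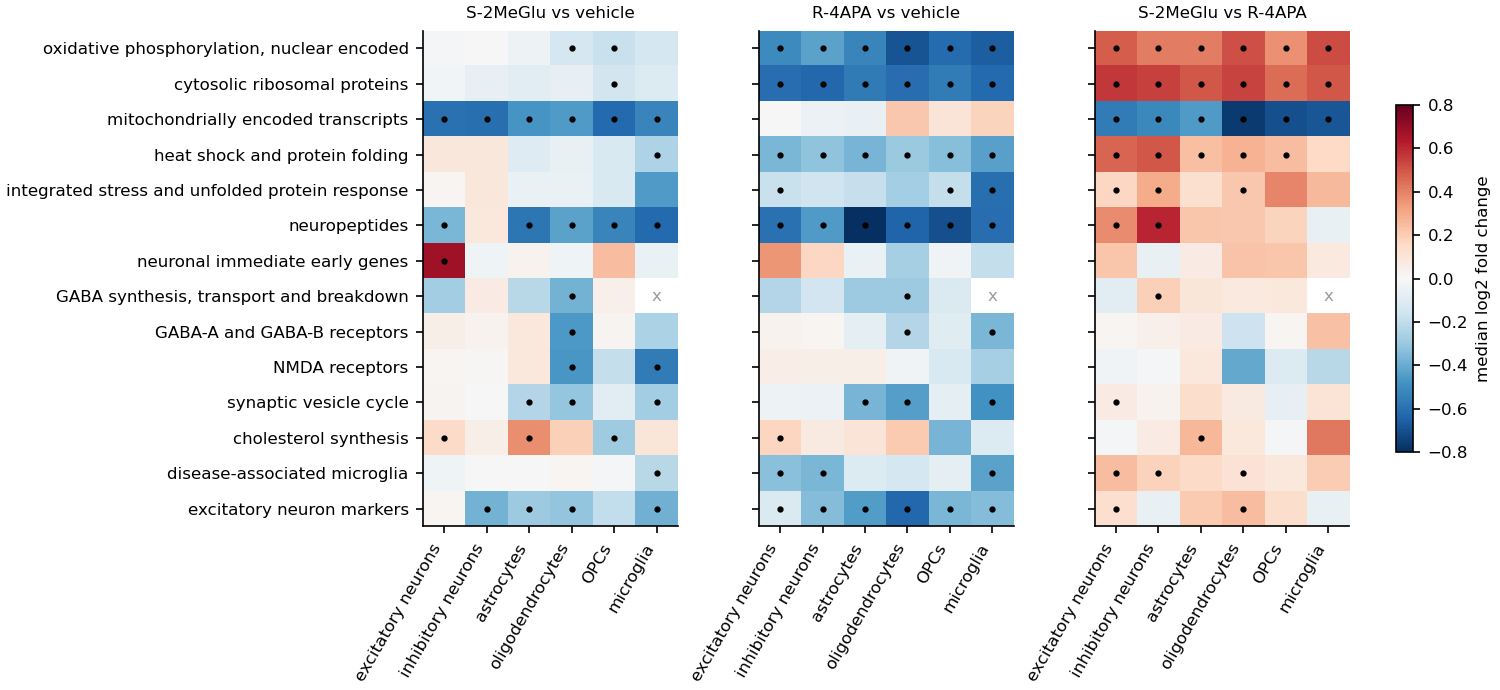
Median log2 fold change (colour) of 14 gene lists (vertical axis) in 6 classes (horizontal axis) for each comparison, with a dot where camera's adjusted p was under 0.05 and a cross where a list was not tested. The oxidative phosphorylation list has medians from -0.69 to -0.43 under R-4APA against vehicle.

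Genes that handle or receive glutamate and GABA were read in their main class in each comparison, S-2MeGlu against vehicle, R-4APA against vehicle and S-2MeGlu against R-4APA in that order. Slc17a7, the vesicular glutamate transporter of cortical excitatory neurons (ENSMUSG00000070570, chromosome 7, 45163949 to 45176142), had log2 fold changes of 0.04 (95% interval -0.14 to 0.22), -0.34 (95% interval -0.52 to -0.16) and 0.38 (95% interval 0.21 to 0.54), at 287 ± 8.63 CPM under S-2MeGlu, 280.1 ± 24.4 in vehicle and 221 ± 18.4 under R-4APA. The difference between the compounds passed (edgeR adjusted p = 0.0183) but not without S-2MeGlu 1, R-4APA 2 or R-4APA 3, where it reached 0.116 (range over the alternatives 0.000899 to 0.116). Against vehicle R-4APA missed over all genes (0.0678), passed adjusted over the list alone (0.00699), and over all genes without Vehicle 2 or S-2MeGlu 3 (smallest 0.0426; range over the alternatives 0.0247 to 0.52). Gad2, one of the enzymes that make GABA (ENSMUSG00000026787, chromosome 2, 22622205 to 22693874), had 0.06 (95% interval -0.12 to 0.24), -0.33 (95% interval -0.51 to -0.15) and 0.39 (95% interval 0.23 to 0.55) in inhibitory neurons, at 294 ± 15.5, 281 ± 7.57 and 225 ± 10.3 CPM. Its difference between compounds passed (edgeR adjusted p = 0.0108) but not without R-4APA 2 or R-4APA 3 (range over the alternatives 0.000643 to 0.0719). R-4APA against vehicle passed adjusted over the list alone (0.00445, with 0.0858 over all genes), and over all genes without S-2MeGlu 3 (range over the alternatives 0.0297 to 0.815). Gad1 had 0.22 (95% interval -0.02 to 0.46), -0.08 (95% interval -0.32 to 0.16) and 0.30 (95% interval 0.09 to 0.52), the last with an edgeR adjusted p of 0.183 over all genes and 0.0228 adjusted over the list alone.

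The remaining genes of this set that are given here did not pass in any of the 3 comparisons over all genes. In excitatory neurons the NMDA receptor genes had -0.00 (95% interval -0.17 to 0.16), 0.10 (95% interval -0.06 to 0.27) and -0.11 (95% interval -0.25 to 0.04) for Grin1 and 0.08 (95% interval -0.08 to 0.24), 0.02 (95% interval -0.14 to 0.18) and 0.06 (95% interval -0.08 to 0.20) for Grin2a. In inhibitory neurons the GABA-A receptor gene Gabrb2 had 0.04 (95% interval -0.14 to 0.21), 0.10 (95% interval -0.08 to 0.27) and -0.06 (95% interval -0.22 to 0.10). In astrocytes the glutamate transporter genes had 0.04 (95% interval -0.26 to 0.33), -0.04 (95% interval -0.33 to 0.25) and 0.07 (95% interval -0.19 to 0.34) for Slc1a2 and -0.01 (95% interval -0.30 to 0.28), -0.05 (95% interval -0.34 to 0.24) and 0.04 (95% interval -0.21 to 0.30) for Slc1a3, and Glul, for glutamine synthetase, had 0.11 (95% interval -0.21 to 0.42), -0.08 (95% interval -0.39 to 0.23) and 0.18 (95% interval -0.10 to 0.46). The GABA transporter gene Slc6a11 had 0.04 (95% interval -0.59 to 0.66), -0.27 (95% interval -0.89 to 0.35) and 0.31 (95% interval -0.24 to 0.87) in astrocytes, and Abat, for GABA transaminase, had 0.28 (95% interval -0.07 to 0.64), 0.08 (95% interval -0.27 to 0.43) and 0.21 (95% interval -0.10 to 0.51). The AMPA receptor gene Gria2 had 0.12 (95% interval -0.16 to 0.40), 0.11 (95% interval -0.17 to 0.39) and 0.01 (95% interval -0.25 to 0.26) there. The list of 10 NMDA receptor genes had medians of 0.01, 0.06 and -0.03 in excitatory neurons. Their camera adjusted p was 0.781, 0.408 and 0.662. The list of 16 GABA-A and GABA-B receptor genes had medians of 0.03, 0.01 and 0.04 in inhibitory neurons, with a camera adjusted p of 0.863, 0.685 and 0.562.

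**Figure D4:**
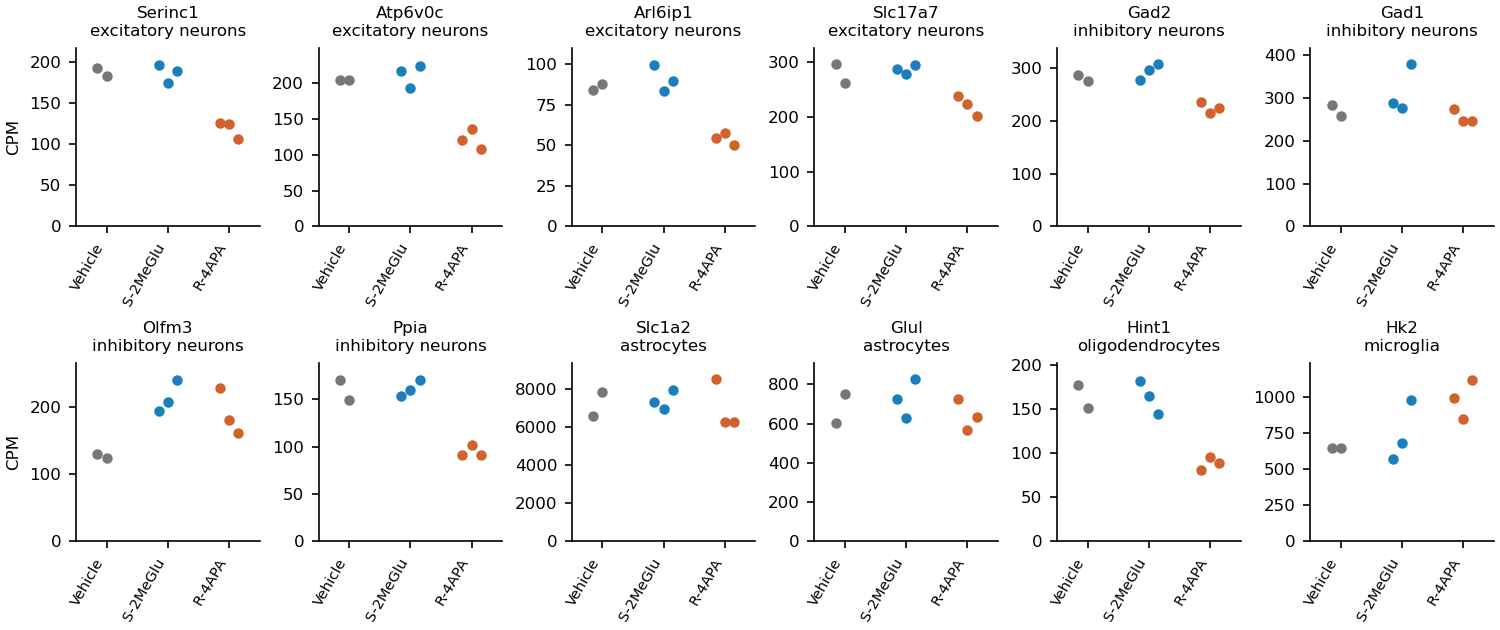
CPM (vertical axis from 0) of 12 genes in the class given above each panel, 1 point per library, for vehicle, S-2MeGlu and R-4APA. Serinc1 and Atp6v0c lie lower in all 3 R-4APA libraries than in the others.

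Fold changes of the compounds against vehicle were correlated across genes, although both share the vehicle mice and genes are not independent replicates. Pearson's r was 0.49, 0.50, 0.60, 0.531, 0.561 and 0.532 in excitatory neurons, inhibitory neurons, astrocytes, oligodendrocytes, OPCs and microglia. The mean of 20 simulated pairs of unchanged groups against these vehicle libraries was 0.622, 0.599, 0.638, 0.559, 0.569 and 0.559. The covariance minus the simulated covariance, which estimates the shared effect, was -0.00473, -0.00292, 0.000384, 0.00584, 0.0070 and 0.0102. The SD of the simulated covariance was 0.00121, 0.0012, 0.00211, 0.00111, 0.00209 and 0.00269. The vehicle libraries could not be split into parts of at least 2, and since simulated unchanged groups gave a higher r in all 6 classes, the shared controls can account for r. Since edgeR called 0 genes for S-2MeGlu against vehicle, with 373 to 509 genes at an unadjusted p under 0.05 and 6, 2, 0, 0, 0 and 0 calls by DESeq2, no overlap of calls could be counted.

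The share of each class among named nuclei was compared between groups with two-sided exact permutation tests, whose smallest possible p is 0.1 for 3 libraries against 2 or 3, so that no share could pass. Astrocytes made up 5.34 ± 0.454%, 6.19 ± 0.726% and 7.6 ± 0.521% of nuclei in vehicle, S-2MeGlu and R-4APA (mean ± SD). Their share was higher in each R-4APA library than in any vehicle or S-2MeGlu library, by 2.26 percentage points over vehicle on average (exact permutation p = 0.1 for both comparisons, adjusted p = 0.825 over 33 tests). Excitatory neurons made up 39.9 ± 12.3%, 46.4 ± 10.4% and 41.6 ± 4.48%, inhibitory neurons 9.28 ± 0.17%, 9.02 ± 0.798% and 9.11 ± 0.883%, oligodendrocytes 23.6 ± 8.21%, 19.4 ± 5.57% and 18.4 ± 1.48%, OPCs 4.13 ± 0.775%, 3.92 ± 0.963% and 3.44 ± 0.225% and microglia 5.86 ± 0.185%, 4.84 ± 1.48% and 5.58 ± 0.474%. Perivascular macrophages made up 0.296 ± 0.342%, 0.392 ± 0.154% and 0.203 ± 0.0135%, with every S-2MeGlu library above every R-4APA library (exact permutation p = 0.1). Endothelial cells made up 0.182 ± 0.0256%, 0.771 ± 0.646% and 0.379 ± 0.11%, mural cells 0.36 ± 0.0204%, 0.366 ± 0.14% and 0.434 ± 0.135% and leptomeningeal fibroblasts 0.533 ± 0.471%, 1.13 ± 0.37% and 0.848 ± 0.331%. Striatal projection neurons, which a cortical dissection can include and which here take in a cluster of 466 nuclei with 0 of the listed striatal markers among its 10 leading genes, made up 10.6 ± 1.7%, 7.52 ± 4.54% and 12.4 ± 2.87%. Clusters left unnamed or left out for holding under 5 nuclei in a library held 17.2 ± 10.6%, 18.1 ± 13.1% and 13.8 ± 0.596% of retained nuclei in vehicle, S-2MeGlu and R-4APA, and the test for free RNA removed 25.1% of the candidate excitatory nuclei of R-4APA 3, both of which can set these shares.

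**Figure D5:**
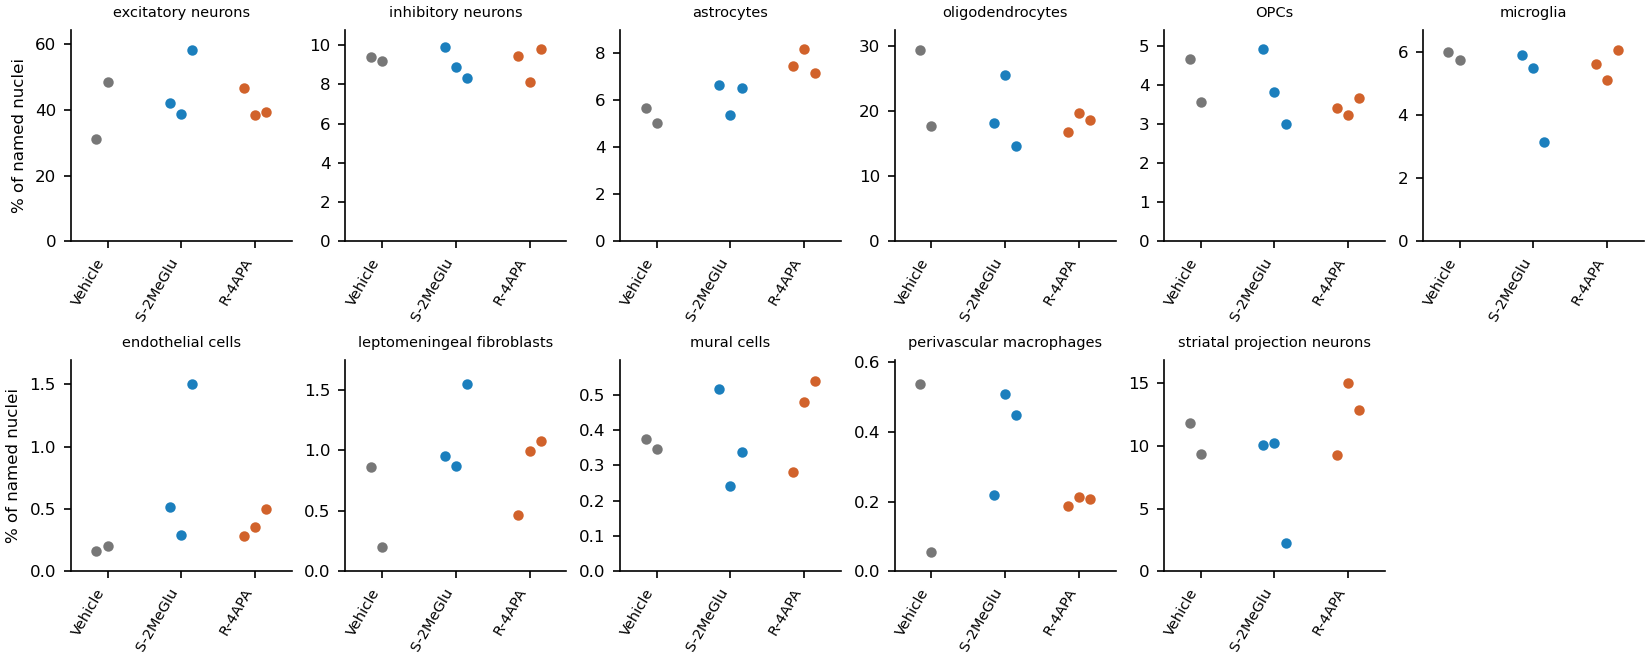
Share of named nuclei (percent, vertical axis from 0) in each class, 1 point per library, for vehicle, S-2MeGlu and R-4APA. Astrocyte shares of the 3 R-4APA libraries lie above those of the other libraries.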

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

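The tests of free RNA, of UMIs per nucleus and of lower expression in the cells, and all shares of left-out clusters, were chosen only after the result was seen, while the tests of cluster composition and of other splits were fixed before.

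The nuclear-encoded oxidative phosphorylation list was lower in all 6 classes under R-4APA against vehicle, with median log2 fold changes of -0.51, -0.43, -0.53, -0.69, -0.62 and -0.66 in excitatory neurons, inhibitory neurons, astrocytes, oligodendrocytes, OPCs and microglia, and the ribosomal protein list moved with it (both at adjusted p = 0.415, 0.451, 0.592, 0.41, 0.459 and 0.334 with an estimated correlation). A different cluster composition within the class is argued against, since matching the clusters moved the median toward zero by over 50% in 0 of 6 classes (-0.52, -0.47, -0.55, -0.62, -0.71 and -0.77), and so are UMIs per nucleus, since the deepest and the shallowest R-4APA library both lay below both vehicle libraries in 6 of 6 classes. Free RNA in the droplets remains a candidate explanation: subtracting it moved the median by over 50% of its size in 5 of 6 classes, past zero in each, to 0.11, 0.19, 0.16, 0.41 and 0.03, which in oligodendrocytes overshoots from -0.69 to 0.41, and moved microglia by 49.9% to -0.33 over 24 of 50 members (camera adjusted p = 0.052, range 3.1e-21 to 0.052 over the alternatives). Lower expression in the cells cannot be told apart from it, as free RNA comes from the same tissue. The list's share of free RNA was below both vehicle libraries in 3 of 3 R-4APA libraries. Lower expression before freezing and a different carry-over of cytoplasmic RNA, which was not measured, both remain open.

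The 6 compound libraries split into groups of 3 in 10 ways, so the smallest share a real grouping can reach is 1 in 10. These splits can neither exclude nor establish chance. The real grouping of S-2MeGlu against R-4APA called 569, 249, 87 and 46 genes in excitatory neurons, inhibitory neurons, oligodendrocytes and microglia with edgeR, where the highest other split called 1, 1, 1 and 5, so that 1 of 10 splits reached the real count in each. In astrocytes and OPCs the real grouping called 0 genes (850 and 624 had an unadjusted p under 0.05, and DESeq2 called 15 and 0), all 10 splits reached that, and the highest other split called 12 and 1. The split with 12 calls in astrocytes set S-2MeGlu 1, R-4APA 1 and S-2MeGlu 2 against the others and had the 5 calls in microglia. This would point to a structure of the samples other than the compound. Simulated data with no change gave 8 calls in astrocytes and 0 in microglia for this comparison, so that the 12 were not separated from false calls, and what those 3 libraries share was not tested.

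Among clusters left out of the class comparisons, a cluster led by Abi3bp, Ndst4, Tfap2d and Bmpr1b (cluster 35) held at least 1.02% of retained nuclei in every R-4APA library (1.22 ± 0.299%, n = 3), 0.352 and 0.394% in the vehicle libraries and 0.786, 0.343 and 0.0436% in S-2MeGlu 1 to 3. No comparison of the report used these nuclei. A cluster that met the astrocyte rule, led by Myoc, Gfap, Aqp4, Clu and Apoe (cluster 59) and left out for libraries with under 5 nuclei such as Vehicle 2 with 3, held at least 0.145% in every S-2MeGlu library (0.305 ± 0.151%, n = 3), 0.0492 and 0.106% in the vehicle libraries and 0.0537, 0.0617 and 0.0711% in R-4APA 1 to 3. The tissue taken differed between mice: cluster 28, led by Glis3 and C1ql2, held 3.69% in Vehicle 1, 2.38 and 3.89% in S-2MeGlu 1 and 2 and at most 0.0119% in the other 5 libraries, and cluster 31, with Fibcd1, 2.52% in Vehicle 1, 3.20, 2.40 and 1.07% in S-2MeGlu 1 to 3 and at most 0.0268% in Vehicle 2 and the R-4APA libraries. Vehicle 2, nearly without both, still had a higher oxidative phosphorylation share in excitatory neurons (0.254%) than R-4APA 1 to 3 (0.184, 0.208 and 0.199%), while what else the dissection changed was not tested.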

How the results depend on the processing

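Keeping nuclei with at least 1500 UMIs whatever the ambient test gave, and subtracting free RNA, are tests chosen only after the result was seen; the others were fixed before. Counts below are genes called with edgeR unless DESeq2 is named, and lists of 6 follow the order excitatory neurons, inhibitory neurons, astrocytes, oligodendrocytes, OPCs and microglia. S-2MeGlu against vehicle called 0 in each class at the main settings (unadjusted p under 0.05 for 416, 459, 429, 509, 425 and 373). R-4APA against vehicle called 263, 119, 31, 211, 10 and 107 (2302, 1497, 912, 1390, 809 and 875), and S-2MeGlu against R-4APA 569, 249, 0, 87, 0 and 46 (2708, 1673, 850, 1075, 624 and 669). Counts are given only where they left the main side of the threshold or moved by over 1.5 times, and correlations and shares where they moved by more than the spread between simulations or replicates. For those below that no smaller number of genes or libraries explains, the cause was not tested.

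S-2MeGlu against vehicle called 2, 15, 15, 2 and 8 genes in excitatory neurons, inhibitory neurons, oligodendrocytes, OPCs and microglia with no filter on low counts. DESeq2 called 6 and 2 in the neurons. With only the 2 groups compared, inhibitory neurons had 2, oligodendrocytes 1 and microglia 5. Composition-matched nuclei gave 1 in excitatory neurons, 1 in inhibitory neurons and 8 in OPCs. Microglia had 1 with at least 1000 genes per nucleus and 2 with doublets kept.

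R-4APA against vehicle called 425, 353, 103, 457 and 73 in the first 5 classes with no filter on low counts. DESeq2 called 486 in excitatory neurons, 1 in OPCs and 30 in microglia. With only the 2 groups compared, 167, 1, 78, 4 and 50 were called in excitatory neurons, astrocytes, oligodendrocytes, OPCs and microglia. RLE normalization gave 12 in astrocytes, and doublets kept gave 19 there. With at least 1000 genes per nucleus, astrocytes had 66, oligodendrocytes 339 and microglia 162. Composition-matched nuclei gave 83 in oligodendrocytes, 28 in OPCs and 66 in microglia. Subtracting free RNA left 4, 0, 0, 0, 0 and 8, and the median log2 fold change of the main calls went from -0.61, -0.68, -0.92, -0.78, -1.10 and -0.89 to -0.31, -0.35, -1.09, -0.15, -1.25 and -1.19 over those still tested. The medians before and after cover different genes, so they do not show whether the changes shrank.

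S-2MeGlu against R-4APA called 510, 72, 276 and 24 in inhibitory neurons, astrocytes, oligodendrocytes and OPCs with no filter on low counts. DESeq2 called 15 in astrocytes and 14 in microglia. With at least 1000 genes per nucleus, astrocytes had 23, oligodendrocytes 141 and OPCs 2. Composition-matched nuclei gave 14 in astrocytes (down-sampling only) and 8 in OPCs. OPCs had 5 with only the 2 groups compared. Subtracting free RNA gave 70, 7, 1, 0 and 4 in excitatory neurons, inhibitory neurons, astrocytes, oligodendrocytes and microglia, with medians of the calls from 0.54, 0.59, 0.69 and 0.84 to 0.44, 0.57, 0.31 and 1.60 in the neurons, oligodendrocytes and microglia.

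Replicate numbers are shared between the groups but do not pair the mice: the deviations of same-numbered libraries from their group means correlated at r between -0.146 and 0.0588 over 42 pairs, 0 of them over 0.1. With the replicate block, R-4APA against vehicle called 0, 69, 1, 48, 16 and 56, and S-2MeGlu against R-4APA called 316, 4, 2 and 21 in excitatory neurons, oligodendrocytes, OPCs and microglia.

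Leaving out each library in turn gave, for S-2MeGlu against vehicle, 0 to 2, 0 to 2, 0 to 1, 0 to 3, 0 to 1 and 0 to 7 calls. R-4APA against vehicle gave 0 to 474, 0 to 226, 0 to 41, 0 to 259, 0 to 72 and 8 to 174, and S-2MeGlu against R-4APA 77 to 728, 54 to 378, 0 to 13, 0 to 148, 0 to 10 and 1 to 85. Without 1 vehicle library a single one is left, which is assumed to vary like the other groups.

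Pairs of gene list and class that passed with camera were 0, 0 and 0 in the 3 comparisons with an estimated correlation, against 47, 54 and 45. They were 8 for S-2MeGlu and 30 for R-4APA against vehicle with free RNA subtracted, and 29 to 62 over the leave-one-out fits of S-2MeGlu against vehicle. RLE normalization turned the direction of 0 list medians. The correlation of the 2 compounds' fold changes, with unchanged groups simulated only at the main settings, was 0.509, 0.529, 0.577, 0.542, 0.623 and 0.603 with composition-matched nuclei. It was 0.50 in excitatory neurons with the ambient test waived, and 0.546 and 0.559 in oligodendrocytes and microglia with at least 1000 genes per nucleus. Over the leave-one-out fits it lay between 0.374 and 0.824, 0.382 and 0.760, 0.456 and 0.792, 0.450 and 0.699, 0.490 and 0.743, and 0.462 and 0.722. With at least 1000 genes per nucleus the difference in the share of microglia was -1.09 points for R-4APA against vehicle and 0.352 for S-2MeGlu against R-4APA.

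Of the 84 calls of genes under the naming rule, 81 were kept with RLE normalization, 80 with no filter on low counts, 71 with DESeq2, 84 with under 1% mitochondrial UMIs, 79 with the ambient test waived and 77 with doublets kept. The replicate block kept 49, composition-matched nuclei 56 of 83, only the 2 groups compared 66 of 83 and at least 1000 genes per nucleus 72 of 83. After free RNA was subtracted 7 of 78 were kept and 2 changed sign: Ndufa13 at 0.24 in excitatory neurons and Hint1 at 2.44 in oligodendrocytes, both for R-4APA against vehicle. Leaving out R-4APA 1 to 3 kept 52, 50 and 27, S-2MeGlu 1 to 3 47, 51 and 70, and Vehicle 1 and 2 47 and 75. For S-2MeGlu against vehicle, planted 1.5-fold changes were recovered for 36% of genes in excitatory neurons and 5% in OPCs.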

Other observations

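The tests in cell populations other than the 6 classes were all chosen only after the result was seen. They used the same edgeR fit on counts summed per library, without leave-one-out fits, subtraction of free RNA or a check that libraries do not overlap, and the genes given were picked, after their values were seen, from the 3 of smallest p in each direction. Among excitatory neurons, R-4APA against vehicle lowered 137 and raised 13 genes in layer 6 corticothalamic cells (n = 3 and 2). The counts were 85 and 5 in layer 4/5 intratelencephalic cells, and 42 and 3 in those of layer 2/3. Layer 5 and layer 6 intratelencephalic cells had 23 lower calls each and layer 6b cells 2. Layer 5/6 near-projecting cells had 0 calls with edgeR (449 genes at an unadjusted p under 0.05; DESeq2 was not run). Layer 5 extratelencephalic neurons (cluster 22, 0 listed markers among its 10 leading genes, 43 nuclei in Vehicle 1) had 20 lower and 2 higher calls. Nr4a3, an immediate early gene, rose there by a log2 fold change of 2.54 ± 0.43 (edgeR adjusted p = 0.00823), and Serinc1 fell by 0.83 ± 0.14 (0.00575). Zfpm2, a zinc finger gene, fell there under S-2MeGlu by 0.90 ± 0.16 against vehicle (edgeR adjusted p = 0.0375) and by 1.16 ± 0.14 against R-4APA (1.3e-05). In layer 6 corticothalamic cells Rxfp1, a relaxin receptor gene, had a log2 fold change of -1.89 ± 0.27 and Cpne4 of -1.21 ± 0.23 for S-2MeGlu against R-4APA (edgeR adjusted p = 0.000611 and 0.0033).

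In inhibitory subtypes R-4APA against vehicle lowered 24 genes in Pvalb cells, 19 in Sst cells and 18 in Vip cells, and edgeR called 0 in Lamp5 cells (583 at an unadjusted p under 0.05; DESeq2 was not run). Olfm3 passed in Sst cells under S-2MeGlu, where it rose by 0.80 ± 0.15 against vehicle (edgeR adjusted p = 0.0365). Slc32a1 was higher under S-2MeGlu than R-4APA in Sst cells at 0.87 ± 0.15 (0.00312). Trpm3, a cation channel gene, was lower in Lamp5 cells at -1.52 ± 0.25 (edgeR adjusted p = 0.000835). Striatal projection neurons, which lie outside the cortex, were present in every library, with 101 to 929 nuclei. R-4APA against vehicle lowered 97 genes in them and raised 1, Adamts19, at 2.03 ± 0.36 (edgeR adjusted p = 0.0205). Adamts19 is also a leading gene of left-out cluster 33, which held 4.78, 0.262 and 0.972% of R-4APA 1 to 3 and 0.218 to 0.345% of the vehicle and S-2MeGlu libraries, so free RNA of that population was not excluded. In the same cells Atp6v0c fell by 0.74 ± 0.10 (0.00963). The striatal nuclei include cluster 32, 466 nuclei with 0 striatal markers and 2 markers of another class among their 10 leading genes. Fitted alone, clusters 7 and 9 had 45 and 47 lower and 3 and 1 higher calls. The oxidative phosphorylation list had a median log2 fold change of -0.56 there (camera adjusted p = 2.3e-26), which was not repeated with an estimated correlation.

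Clusters left unnamed or left out for holding under 5 nuclei in a library held 24.7 and 9.65% of retained nuclei in Vehicle 1 and 2, 25.9, 25.3 and 3.01% in S-2MeGlu 1 to 3 and 14.1, 13.2 and 14.3% in R-4APA 1 to 3. Cluster 10, led by Chchd10, Atp5e, Cox5b and other respiratory chain genes, held 0.792 and 0.131% in Vehicle 1 and 2, 0.222, 0.217 and 0.479% in S-2MeGlu 1 to 3 and 0, 0.0154 and 0.0474% in R-4APA 1 to 3. Of its candidates 93.6% failed the ambient test. Cluster 38, led by Ccbe1 and Shisa6, held 1.48% in Vehicle 1, 1.35, 1.25 and 0.196% in S-2MeGlu 1 to 3 and at most 0.0164% in Vehicle 2 and the R-4APA libraries.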
